A study of Mus musculus with 8 samples.

How the data were processed

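RNA was measured by sequencing in epididymal white adipose tissue (eWAT, the fat pad beside the epididymis) of 8 obese male mice on a C57BL/6 background. Per the labels' protocols the fat was flash frozen, RNA was taken with Trizol, and libraries were made with the Illumina TruSeq RNA kit. The 4 WT mice carried 2 floxed copies of Slc16a1 and no Cre. The 4 AKO mice carried the same floxed copies plus the AP2-Cre transgene, in which Cre is driven by the promoter of the adipocyte gene Fabp4 (aP2). Presence of Cre and the intended deletion therefore go together in this design. WT mice have the numbers 2, 3, 4 and 5 and AKO mice the numbers 3, 8, 9 and 11, as in the labels. The groups share only number 3, on different animals. The series design text describes separate mice, so p-values cover the spread between these 4 and 4 animals.

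The authors deposited 1 table per library with 152298 rows, in the same order in every table, each row a gene identifier and a value. The deposited values are TPM (transcript abundance scaled to a fixed total). They sum to 1000000 in each library within rounding, are given in steps of 0.01, and have 1 row per transcript, so that 21578 genes have more than 1 row. HISAT2, DESeq2 and the mouse build mm9 are named per the submitters' processing notes, without a role or version. The quantifier and the annotation are not given in the sources used here. TPM keeps no read depth, so the depth per library is unknown and no counting interval is given. Between 13968 and 14884 genes per library reached 1 TPM. Mitochondrial genes held between 6.69% and 8.99% of TPM.

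Rows do not say which transcript they stand for. They are numbered here in the order in which they follow each other under one gene identifier. A gene's value is the sum of its rows. A row listed at 0 can be a failed estimate as well as an absent transcript. Of 55487 gene identifiers, 55141 had a symbol in the gene name table used. Another 401 rows carry locus identifiers without a gene (0.605% to 0.943% of TPM) and were left out of the gene tests. The identifiers go beyond an mm9-era gene set, and the annotation at hand is GENCODE M21, built on another assembly. It was used for names, chromosome names and gene order only, and no coordinates are given. No 2 libraries held identical values.

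The design fixed before the data were examined named a count test, with limma for normalized values. The deposited unit being TPM, limma (version 3.58.1, R 4.3.3) was fitted with a mean-variance trend to log2(TPM + 1). Genes with at least 1 TPM in at least 4 samples were tested, which kept 14172 genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an FDR of 0.05. A log2 fold change is AKO minus WT on the log2(TPM + 1) scale, and this scale understates the change of low genes. The design also said that the row with the highest mean stands for a gene. That rule assumed 1 row per gene, so the sum was used and the highest row became an alternative. Rows were also tested singly (33323 rows), a test added after the files were seen. Single values were compared with two-sided exact permutation tests over the 70 arrangements of 4 and 4, whose smallest possible p is 0.0286.

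A set of 35 gene lists was fixed before the data were examined. Lists with at least 4 tested members, 33 of them, were tested with camera at a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were set as alternatives. A list score is the mean log2(TPM + 1) of its members in 1 mouse.

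Genes named in the text follow a rule fixed beforehand. Slc16a1 and 6 lactate genes are named whatever their result. Up to 12 genes per direction are named that pass the threshold, have a mean log2 of at least 1 and groups that do not overlap, leaving out symbols made of Gm and digits, symbols ending in Rik and identifiers with no symbol. Where fewer than 5 pass in a direction, the 5 with the smallest p are given instead. For each list up to 4 members with the smallest p are named. Genes and rows outside that rule are said to be chosen after their values were seen.

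Alternatives tried were a pseudocount of 0.1, no filter, leaving out each mouse (keeping the genes tested over all 8), the 2 other list tests, and, added after seeing the data, the highest row per gene, median-ratio scaling, leaving out mitochondrial genes, sample quality weights, a robust spread, and exact permutation of the list scores. The fit was tested on simulated data for 14172 genes in 4 and 4 samples with 200 genes of moderate or high level changed: 77% of those changed by 1 and 94% of those changed by 2 on the log2 scale were recovered, and 5 unchanged genes were called. The genes called in the real data had mean log2 values from 0.75 to 2.85, below those of the changed genes. Recovery at their level was therefore not tested. A list shifted by 0.5 was called and 0 other lists were. The simulated noise was drawn separately for each gene, without correlation between genes. The run therefore does not test the list calls at the correlation of the real lists, estimated at up to 0.96. Similar transcripts were searched with BLAST 2.17.0 in the M21 transcripts at 95% identity over at least 100 bases. Other computing used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.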

Results

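Transcript levels were measured in epididymal white fat from 8 obese male mice, 4 WT and 4 AKO. The AKO mice carry a Cre recombinase under the Fabp4 (aP2) promoter, meant to remove Slc16a1 in fat cells. Slc16a1 encodes MCT1, a plasma membrane carrier of lactate, pyruvate and ketone bodies. The single comparison asks how the transcripts of the obese fat pad differ with this intended deletion. Values are TPM, without read depth, and errors are SD over 4 mice per group.

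The total of Slc16a1 (ENSMUSG00000032902) was not lower in the libraries labelled AKO. The summed TPM was 23.4, 28.5, 15.7 and 17.7 in WT mice 2, 3, 4 and 5, and 22.4, 21.5, 27.1 and 25.03 in AKO mice 3, 8, 9 and 11. The group means were 21.3 ± 5.78 (SD, n = 4) in WT and 24.0 ± 2.54 (SD, n = 4) in AKO, a log2 difference of 0.19 (exact permutation p = 0.371, and limma FDR = 0.850 over all genes). The gene total therefore does not check the genotype labels. The tables hold 2 rows for this gene, and the rows moved apart. Row 1 was 14.6 ± 2.88 TPM in WT and 6.61 ± 1.98 in AKO, 45.4% of the WT mean, with each AKO mouse below each WT mouse. Its log2 difference was -1.05, with an exact permutation p of 0.0286, the smallest these 8 mice allow, and 0.0857 after adjustment over the 2 rows and the sum. Among all rows its limma FDR was 0.598. Row 2 was 12.51 and 14.4 TPM in WT mice 2 and 3, was listed at 0 in WT mice 4 and 5, and lay between 13.6 and 22.5 in AKO (exact permutation p = 0.0857). WT mice 4 and 5 also had the 2 lowest totals. A row listed at 0 can be a failed estimate, so the WT mean total depends on these 2 zeros. Which transcript or exon each row covers is not given in the sources used here, so the rows say nothing about the deleted part. GENCODE M21 lists 1 transcript for Slc16a1, so at least 1 of the 2 rows has no counterpart there, and which one is not known. Taking the row with the highest mean in place of the sum gave a log2 difference of 2.24 (FDR = 0.835). The groups are called WT and AKO by their labels throughout.

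**Figure D1:**
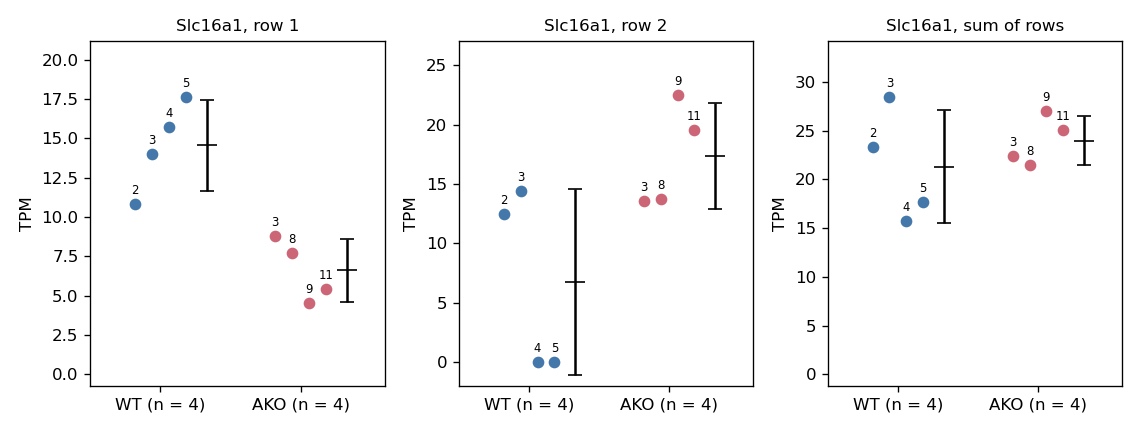
TPM of Slc16a1 per mouse in row 1, row 2 and their sum, for 4 WT (blue) and 4 AKO (red) libraries numbered as in the labels. Black bars are the mean ± SD. Row 1 separates the groups, row 2 is listed at 0 in WT mice 4 and 5, and the sums overlap.

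Few genes passed the threshold. Of 14172 genes tested with limma, 3 were higher in AKO and 1 was lower at an FDR below 0.05, and 5 had an FDR below 0.1. At an unadjusted p below 0.05 there were 673 genes, 366 of them higher and 307 lower. That is fewer than the share of 0.05 of the genes tested that chance alone would give. Groups did not overlap for 157 genes with AKO above and 189 with AKO below, 2.44% of those tested, where chance gives 2.86%.

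Gstm6 (ENSMUSG00000068762, chromosome 3 in GENCODE M21), a glutathione S-transferase of the mu class, was the gene that fell. It had 11.5 ± 1.66 TPM in WT and 3.24 ± 0.486 in AKO, a log2 change of -1.56 (SE 0.13, FDR = 0.00823), and it was lower in 4 of 4 AKO mice than in each WT mouse. Myt1l (ENSMUSG00000061911, chromosome 12), a zinc finger transcription factor best known from neurons, was listed at 0 in the 4 WT libraries and had 1.84 ± 0.267 TPM in AKO (log2 change 1.502 on this scale, SE 0.13, FDR = 0.00892). The other 2 genes that rose are predicted genes outside the naming rule, chosen after their values were seen. Gm40847 (ENSMUSG00000113778, chromosome 12) had 1.53 ± 0.354 TPM in WT and 7.74 ± 1.17 in AKO (log2 change 1.79, FDR = 0.00823). Gm7993 (ENSMUSG00000107092, chromosome 5) had 0.230 ± 0.133 and 2.63 ± 0.401 TPM (log2 change 1.56, FDR = 0.0101). Both predicted genes share long stretches with other M21 genes, 73.4% and 100% of their longest transcript at 95% identity, so their levels are uncertain. Myt1l and Gstm6 had 0% in such stretches. Gstm6 lost the threshold without AKO mouse 3 (FDR = 0.0595), Myt1l without WT mouse 2 (0.0522), AKO mouse 3 (0.0617) or AKO mouse 11 (0.0683), and Gm7993 without WT mouse 2 (0.0575), AKO mouse 3 (0.0617), AKO mouse 9 (0.0717) or AKO mouse 11 (0.0683).

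**Figure D2:**
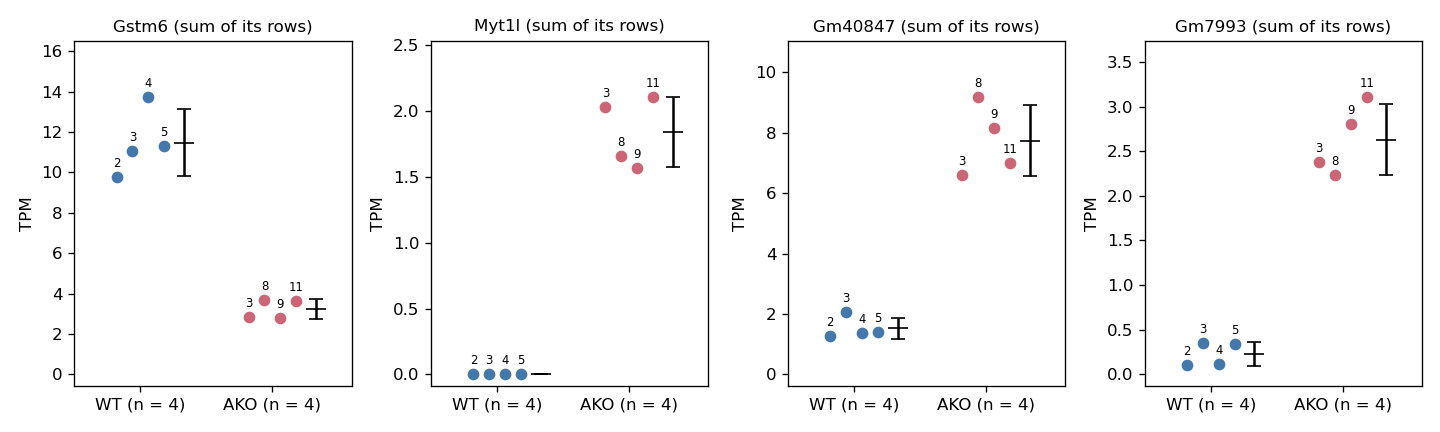
TPM per mouse of the 4 genes with an FDR below 0.05, for 4 WT (blue) and 4 AKO (red) libraries numbered as in the labels. Black bars are the mean ± SD. Gstm6 is lower and Myt1l, Gm40847 and Gm7993 are higher in each AKO mouse than in each WT mouse.

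The named genes with the next smallest p did not pass. Those with higher values include the immunoglobulin light chain genes Igkv12-89 (1.22 ± 0.762 TPM in WT and 13.5 ± 6.48 in AKO, FDR = 0.0722) and Iglc3 (0.915 ± 0.378 and 3.12 ± 0.795, FDR = 0.317). They belong to families of near-identical segments, so single-gene values are uncertain. Ssh1, a cofilin phosphatase, had 9.32 ± 1.39 TPM in WT and 16.6 ± 2.26 in AKO (FDR = 0.397). The pseudogene Hmgn2-ps1 was listed at 0 in WT and had 2.18 ± 1.29 TPM in AKO (FDR = 0.296). Among those with lower values, Zfp125 had 10.98 ± 0.776 TPM in WT and 5.76 ± 0.991 in AKO (FDR = 0.189). Camk2b, a calcium/calmodulin-dependent kinase subunit, had 24.7 ± 8.37 and 10.04 ± 2.67 (FDR = 0.533). The translation initiation factor gene Eif2b1 had 33.4 ± 1.06 and 26.6 ± 0.815 (FDR = 0.533), and N4bp2l2 had 31.3 ± 4.59 and 18.2 ± 3.40 (FDR = 0.535).

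Tested singly, 5 of 33323 transcript rows were higher in AKO and 2 lower. These rows were chosen after their values were seen. Row 3 of Fabp4, the fatty acid binding protein gene whose promoter drives Cre in the AKO mice, had the smallest p. It held 0.220 ± 0.0980 TPM in WT and 7.40 ± 2.66 in AKO (log2 change 2.74, SE 0.22, FDR = 0.0174). Total Fabp4 did not separate the groups, at 21630 ± 4459 TPM in WT and 22240 ± 3682 in AKO (exact permutation p = 0.743). Row 5 of Gm11747 had 4.93 ± 1.183 TPM in WT and 0.0775 ± 0.155 in AKO (FDR = 0.0174). Row 5 of Rfc3, a clamp loader subunit gene, and row 6 of Pus10, a pseudouridine synthase gene, were listed at 0 in WT and had 2.32 ± 0.607 and 1.90 ± 0.389 TPM in AKO (FDR = 0.0481 for both). The other 3 rows belong to Gm40847, Gstm6 and Gm7993. Rows above 0 numbered 63143 to 66466 per WT library and 66578 to 70720 per AKO library. Calls listed at 0 in WT, Myt1l included, were not separated from this wider difference. With no filter on low values 0 of 99191 rows passed in limma. At an unadjusted p below 0.05 there were 4045, fewer than the share of 0.05 that chance alone would give. With the filter kept, leaving out 1 mouse left between 0 and 2 rows higher and between 0 and 1 lower. The Fabp4 row passed only without AKO mouse 11, and its FDR was between 0.0503 and 0.110 without any 1 of the other mice.

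No gene of lactate handling passed the threshold. Slc16a3 (MCT4) had 3.74 ± 0.650 TPM in WT and 3.59 ± 1.003 in AKO, Slc16a7 (MCT2) 14.0 ± 4.63 and 15.4 ± 3.51, and Bsg, which encodes basigin, the chaperone of MCT1 and MCT4, 508.4 ± 35.8 and 512.9 ± 16.0. The lactate dehydrogenase gene Ldha had 874.2 ± 142.3 and 831.4 ± 68.8, Ldhb 55.5 ± 17.8 and 42.7 ± 13.3, and the lactate receptor gene Hcar1 30.1 ± 8.55 and 32.7 ± 4.28. Each of these 6 had an FDR of at least 0.831. In the list of lactate and pyruvate handling genes, 8 of 14 members were positive and 6 negative (median log2 change 0.05, camera FDR = 0.950), and Pdha1 had the smallest p (146.5 ± 17.9 and 127.8 ± 11.6 TPM). Glycolysis had a median of -0.01 (FDR = 0.828), with a mean above 0 at 0.0026. Its member with the smallest p was Hk2, at 36.6 ± 4.96 TPM in WT and 28.0 ± 4.79 in AKO.

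Macrophage genes were higher as sets in AKO by camera with its preset correlation, and these calls were lost with an estimated one (adjusted p = 0.689 with an estimated correlation for each of the 4 lists of this paragraph). All 12 tested genes of lipid-associated macrophages, cells that gather around dying fat cells in obese fat, had positive log2 changes, with a median of 1.05 (FDR = 3.73e-05). Their estimated inter-gene correlation was 0.94, and that of the general macrophage markers 0.74, against the preset 0.01. Their shared sign is thus not 12 separate observations. All 12 cell cycle genes were positive too (estimated correlation 0.96), without a call (FDR = 0.216). Gpnmb had 477.1 ± 403.3 TPM in WT and 937.0 ± 329.6 in AKO, Ctsk 142.8 ± 98.2 and 299.4 ± 96.3, Itgax 61.0 ± 43.1 and 121.4 ± 37.4, and Spp1 41.5 ± 47.7 and 91.3 ± 31.8. Of 13 general macrophage markers, 12 were positive (median 0.48, FDR = 0.000922). Complement genes C1qb (498.4 ± 185.0 and 715.8 ± 172.0 TPM) and C1qc (323.1 ± 112.2 and 477.2 ± 114.4) and the lysozyme gene Lyz2 (1688 ± 437.7 and 2257 ± 504.0) were among them. Dendritic cell and MHC class II genes were positive for 9 of 9 members (median 0.19, FDR = 0.00355), with H2-Aa at 851.1 ± 37.1 TPM in WT and 1009 ± 143.6 in AKO and H2-Ab1 at 760.1 ± 12.4 and 881.0 ± 118.1. Immediate-early genes were positive for 10 of 11 members (median 0.18, FDR = 0.0332), with Atf3 at 83.0 ± 54.3 and 129.4 ± 41.5 and Junb at 39.3 ± 13.5 and 52.1 ± 15.2.

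Adipocyte and lipid genes were lower as sets in AKO by camera with its preset correlation, and these calls too were lost with an estimated one (adjusted p = 0.689 with an estimated correlation for each of the 4 lists). Of 15 markers of mature fat cells, 14 were negative (median -0.18, FDR = 0.00337). Their estimated inter-gene correlation was 0.57, so these signs are not 15 separate observations either. The lipid droplet coat gene Plin1 had 988.6 ± 173.9 TPM in WT and 779.9 ± 88.2 in AKO, the hormone-sensitive lipase gene Lipe 955.2 ± 234.9 and 721.7 ± 141.0, and Pparg, the adipocyte master regulator, 165.4 ± 20.2 and 146.1 ± 20.2. Of 17 genes of de novo lipogenesis, 15 were negative (median -0.14, FDR = 0.00766). Mlxipl, which encodes the glucose-sensing factor ChREBP, had 25.7 ± 1.67 TPM in WT and 19.1 ± 2.85 in AKO with no overlap, and Acaca had 44.4 ± 12.3 and 32.9 ± 5.49. Triglyceride synthesis and storage had 10 of 14 negative (median -0.12, FDR = 0.0177), with Dgat2 at 2100.0 ± 451.7 and 1530.0 ± 282.3 TPM and Gpam at 54.9 ± 13.6 and 40.8 ± 5.66. Lipolysis had 10 of 13 negative (median -0.14, FDR = 0.0251), with G0s2 at 394.8 ± 57.5 and 336.8 ± 43.1. Plin1 and other members belong to more than 1 of these lists.

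None of these 8 list calls held with fry either. In limma 0 of the 351 distinct list members passed an FDR of 0.05 over all genes. At an unadjusted p below 0.05 there were 21, near the share of 0.05 that chance alone would give. Adjusted over the list alone, 0 members of the 8 lists passed either. WT mouse 4 stood apart, with a lipid-associated macrophage score of 6.34 against 7.67 to 8.90 in the other WT mice and 8.23 to 9.17 in AKO, and an adipocyte score of 10.3 against 9.12 to 9.86 and 9.14 to 9.79. Without it the median of the lipid-associated list was 0.49 (FDR = 0.00282), that of macrophage markers was 0.28 (FDR = 0.0331, and 0.73 without WT mouse 3), and that of adipocyte markers was -0.14 (FDR = 0.120).

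**Figure D3:**
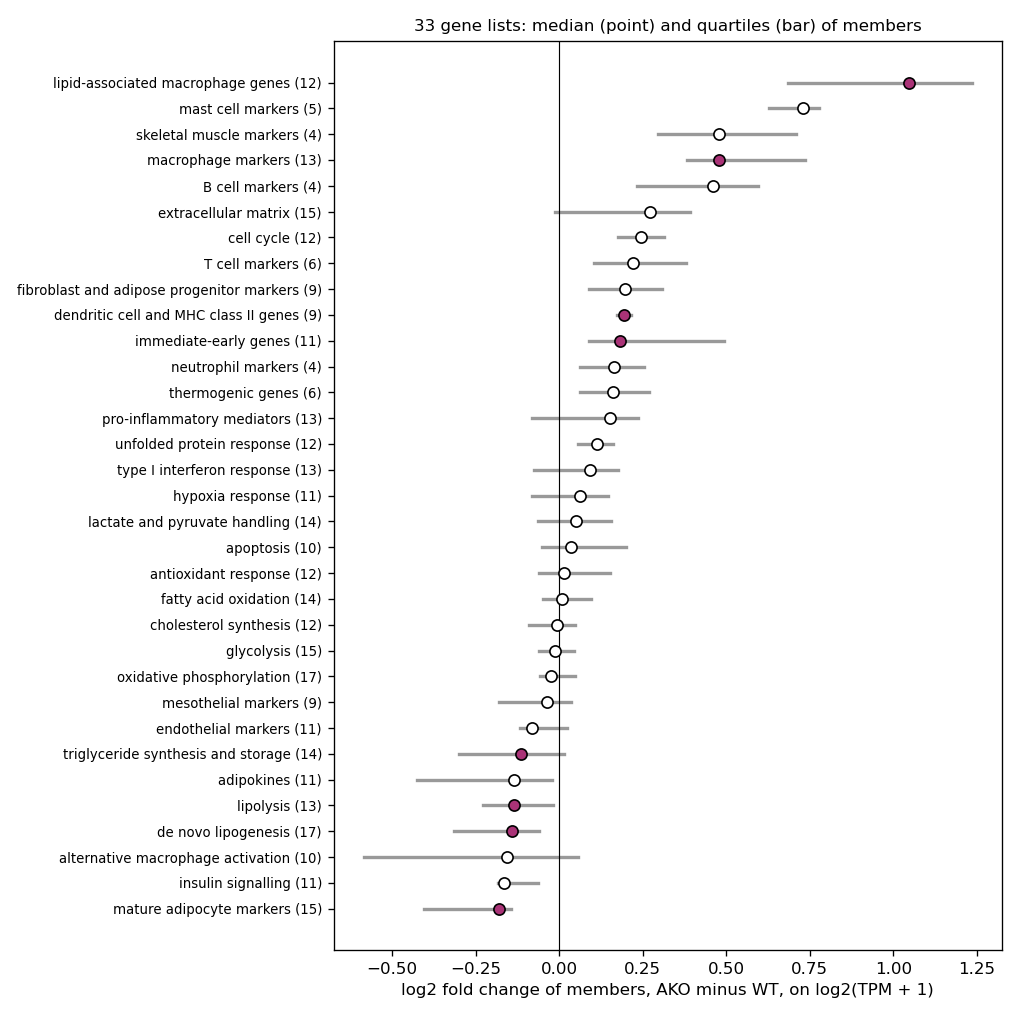
Median log2 fold change, AKO minus WT, of the tested members of each of 33 gene lists (points), with the range from the lower to the upper quartile (grey bars) and the number of tested members in brackets. Filled points are the 8 lists with a camera FDR below 0.05, from 1.05 for lipid-associated macrophage genes to -0.18 for mature adipocyte markers.

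**Figure D4:**
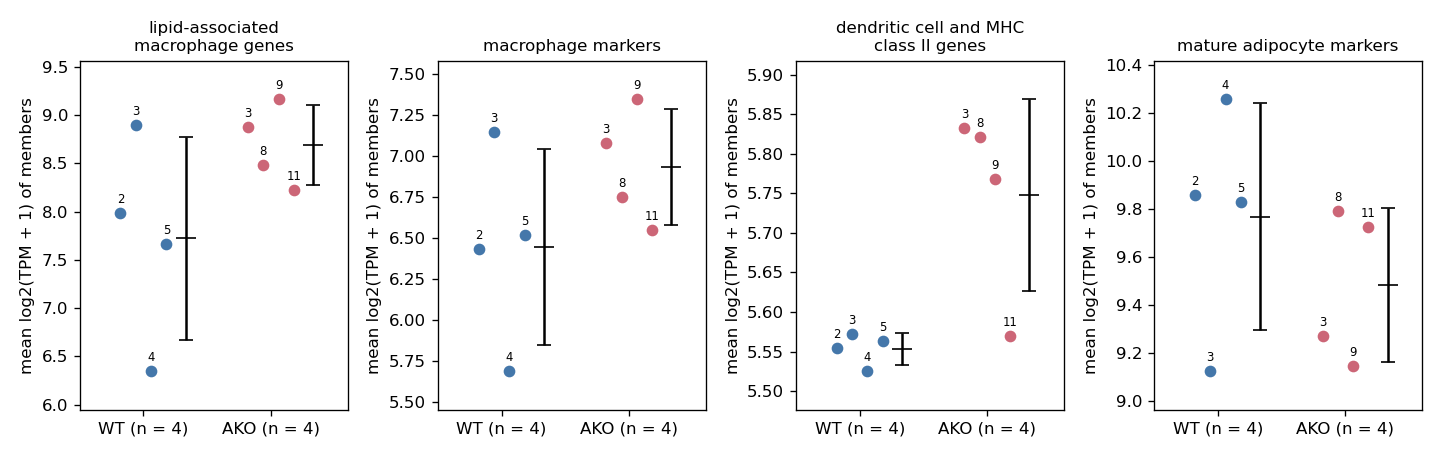
List score per mouse, the mean log2(TPM + 1) of the list's members, for 4 WT (blue) and 4 AKO (red) libraries numbered as in the labels, on axes that do not start at 0. Black bars are the mean ± SD. WT mouse 4 has the lowest macrophage scores and the highest adipocyte score, and the groups overlap in each panel.

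Other immune and tissue lists did not pass. Medians were 0.46 for B cell markers (FDR = 0.0867), 0.22 for T cell markers (0.262), 0.16 for neutrophil markers (0.744), 0.73 for mast cell markers (0.0993), 0.09 for the type I interferon response (0.210), 0.15 for pro-inflammatory mediators (0.410) and -0.16 for alternative macrophage activation (0.0941). The B cell receptor gene Cd79a had 1.44 ± 0.300 TPM in WT and 2.72 ± 0.919 in AKO, the interferon-induced gene Mx1 1.54 ± 0.277 and 3.09 ± 1.01, and Lyve1, a marker of resident macrophages, 30.6 ± 5.33 and 20.4 ± 6.89. Fibroblast and adipose progenitor markers had a median of 0.20 (FDR = 0.0507), with Dcn at 763.2 ± 54.6 and 963.1 ± 137.1 TPM. Extracellular matrix genes had 0.27 (0.119), endothelial markers -0.08 (0.487), mesothelial markers -0.04 (0.744) and skeletal muscle markers 0.48 (0.175). Epididymal epithelium markers had 0 tested members and red blood cell markers 3 (median -0.41), too few for the test.

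Metabolic and stress lists did not pass either. Medians were -0.17 for insulin signalling (FDR = 0.0507), -0.13 for adipokines (0.216), 0.01 for fatty acid oxidation (0.828), -0.03 for oxidative phosphorylation (0.806), -0.01 for cholesterol synthesis (0.744), 0.06 for the hypoxia response (0.828), 0.02 for the antioxidant response (0.837), 0.11 for the unfolded protein response (0.0845), 0.04 for apoptosis (0.845) and 0.25 for the cell cycle (0.216). Thermogenic genes had a median of 0.16 (0.487). Their member Cox7a1, a cytochrome oxidase subunit gene, had 18.6 ± 3.05 TPM in WT and 26.02 ± 3.34 in AKO and was the 1 list member that passed when adjusted over the list alone, with an FDR of 0.831 over all genes.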

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

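The tests of this part were chosen after the results were seen, except the count of splits for the number of genes, which was planned.

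The 4 genes past the threshold are more than other groupings of the mice give. Of the 35 splits of the 8 mice into 4 and 4, 1 gave as many, the real one, and the highest of the other splits gave 2. This argues against a chance division of these mice as the source of the count. It cannot exclude one, because first of 35 is the furthest this test can reach. For transcript rows the real split, with 7, was likewise the 1 split with as many, and the highest of the others gave 5. The real split also separates the libraries by rows above 0, 63143 to 66466 in WT and 66578 to 70720 in AKO. Neither count was separated from that wider difference, so being first of 35 does not tie it to the genotype.

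Slc16a1 row 1 separated the groups while the gene total did not. An unstable split of the gene between its rows, made by the quantification, may contribute. In 2 WT libraries row 2 is listed at 0 where other WT libraries have over 5 TPM, so the reported rows vary within a group. The same 2 libraries have totals of 15.7 and 17.7 TPM, against 23.4 and 28.5 in the other WT libraries. The zeros therefore go with lower totals too, and a change of division alone is not shown. Within AKO, where no row is listed at 0, the rows also went opposite ways. Mice 9 and 11 had 4.51 and 5.43 TPM in row 1 and 22.5 and 19.6 in row 2. Mice 3 and 8 had 8.80 and 7.71 in row 1 and 13.6 and 13.8 in row 2. Row 1 is nevertheless lower in 4 of 4 AKO mice than in each WT mouse. Loss of part of the transcript in the cells where Cre acted, with other cells of the pad keeping the gene, stays open and untested. Which cells of the pad those are was not measured. Neither the transcript behind each row nor reads over the exons were analysed here.

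Macrophage lists were higher and adipocyte and lipid lists lower in AKO, which other groupings of the mice could give: 5 of the 35 splits, the real one included, called the same 2 macrophage lists in one direction and the same 4 adipocyte and lipid lists in the opposite one (the highest other split gave 6 of these lists), so chance cannot be excluded. By number of lists, 22 of the 35 splits gave at least the 8 of the real one, and the highest other split gave 20. Another split, WT mice 2 and 4 with AKO mice 8 and 11 against the rest, gave 18 lists. It gave 3649 genes with an unadjusted limma p below 0.05 (0 at an FDR below 0.05). The real split gave 673 such genes, fewer than chance alone would give. The split with 20 lists gave 401, so many lists did not require many genes. Whether WT mouse 4 alone accounts for the macrophage lists is open: without it the larger FDR was 0.0331 in camera, whose calls end with an estimated correlation, and the score differences of 0.23 (macrophage, WT SD 0.39, AKO SD 0.35) and 0.51 (lipid-associated, WT SD 0.64, AKO SD 0.42), down from 0.49 and 0.97, lie within the spread. For the adipocyte markers the FDR without it was 0.120; their median went from -0.18 to -0.14 and the difference in score from -0.28 (WT SD 0.47, AKO SD 0.32) to -0.12 (WT SD 0.42), so the part played by that mouse is not decided. A lower share of fat cells in the AKO tissue cannot be told apart from a change in macrophages, because macrophage score minus endothelial score differed by less than its spread (exact permutation p = 0.457, 4 and 4 mice). The prediction for a lower share, endothelial markers higher as well, was not met: their median was -0.08, with 8 of 11 negative. Their scores, 6.06 (SD 0.40) in WT and 6.04 (SD 0.20) in AKO, differed by less than the spread, so this does not decide.

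Some of the genes with an unadjusted limma p below 0.01 (115 of 14052 placed genes, without immunoglobulin genes) lay in neighbouring groups. The number 115 is itself no more than the share of 0.01 that chance alone would give. By M21 gene order, windows of 25 tested genes on chromosomes 12 and 2 held 5 each: Gm40847, Gm29737, Gm4425 and Gm38699 with higher values and Zfp125 with a lower one on chromosome 12, and Zfp966, Zfp972, Gm14421, Gm14412 and Gm14327, with lower values, on chromosome 2. Chance placement along the chromosomes is argued against by 10000 shuffles of gene order, of which a share of 0.0043 had as full a window, but 2 of the 35 splits of the mice had a window as full (highest other 5), so a chance division of the mice stays possible. Reads shared between near-identical copies on chromosome 2 may account for that group, where 4 of 5 genes have over 50% of their longest transcript matched in another gene. On chromosome 12 only 1 of 5 has, which argues against sharing over most of the transcript there. Zfp125, Gm4425 and Gm38699 still had 13.5%, 21.1% and 21.8% matched, and Gm29737 0%. Sharing over part of a transcript is therefore not excluded on chromosome 12. Inherited sequence linked to the transgene, or its place of insertion, is a biological explanation that the design allows and that was not tested.

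Of 220 groups of 4 mice examined, 7 held 1 mouse far from the other 3, and chance alone would give about 1 in 20 groups. Iglc3 was 1.48 TPM in WT mouse 3 against 0.690 to 0.770 in the other WT mice, and 4.31 in AKO mouse 8 against 2.69 to 2.76. Ssh1 was 7.26 in WT mouse 3 against 9.78 to 10.2, and Irs2, an insulin receptor substrate gene, was 10.7 in WT mouse 5 against 15.5 to 16.7. Pvalb, a muscle calcium-binding protein gene, was 11.2 in AKO mouse 8 against 25.5 to 26.4, and Bid was 10.7 in AKO mouse 3 against 7.24 to 7.72. The antioxidant response score was 6.97 in AKO mouse 9 against 6.88 to 6.89 in the other AKO mice.

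Among 306 tested rows with a locus identifier and no gene, which the gene comparison leaves out, 3 were higher in AKO (limma, adjusted over these rows). MSTRG.23304 had a mean of 3.18 TPM in AKO against 0 to 0.160 in WT (FDR = 0.000586), MSTRG.4484 a mean of 1.91 where WT is listed at 0 (FDR = 0.00193), and MSTRG.4450 a mean of 7.67 against 0.630 to 2.82 (FDR = 0.0177). Adjustment over 306 rows is milder than over the 33323 rows tested above. These rows were not run under the alternatives. Those at or near 0 in WT were not separated from the larger number of rows above 0 in AKO.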

How the results depend on the processing

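Scaling, row and weight alternatives were chosen after seeing the data. The planned count-based alternatives (DESeq2, limma-voom with and without quality weights, other size factors, count filters, a robust quasi-likelihood fit) were not run, because the tables hold TPM and no counts. No paired analysis was possible because the groups share only number 3, on different animals. Of 74 gene results, 70 stayed on their side of the threshold under each alternative run. Nearly all of these had no call in the main fit. Among the called genes, Gstm6, Myt1l and Gm7993 lost the call without some single mice, as given above, and Gm40847 did not lose it. The Slc16a1 total stayed above 0 and short of the threshold in each, from 0.07 to 0.34 when 1 mouse was left out, and row 1 from -1.18 to -0.91. A pseudocount of 0.1 gave 5 genes higher, 2 rows higher and 0 lower. With no filter 0 rows passed in either direction, and the immediate-early median of 0.18 lost its call (FDR = 0.0540). Quality weights gave 2 rows higher, and a robust spread 2 higher and 1 lower. Leaving out 1 mouse gave 1 to 3 genes higher (1 without WT mouse 2, AKO mouse 3 or AKO mouse 11), 0 to 2 lower (2 without WT mouse 4, 0 without AKO mouse 3), 0 to 2 rows higher and 0 to 1 lower, and 3 lists (without AKO mouse 3) to 16 (without WT mouse 3).

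With an estimated correlation and with fry, 0 lists passed, and the medians of the 8 lists, which neither test alters, are 1.05 (lipid-associated macrophage), 0.48 (macrophage), 0.19 (MHC class II), 0.18 (immediate-early), -0.18 (adipocyte), -0.14 (lipogenesis), -0.12 (triglyceride) and -0.14 (lipolysis). Exact permutation of list scores also gave 0 lists (smallest p = 0.0571). With 33 lists and a smallest possible p of 0.0286, a list could pass this test only if many lists reached that floor together. Its 0 therefore adds little. With the highest row per gene 4 lists passed, and lipogenesis (-0.14), triglyceride (-0.10), lipolysis (-0.14) and immediate-early genes (0.16) did not. The 3 immune lists kept their calls without any 1 mouse, with medians from 0.49 to 1.52, 0.28 to 0.73 and 0.15 to 0.29. Adipocyte markers (-0.42 to -0.14) lost the call without WT mouse 4 or AKO mouse 3, lipogenesis (-0.21 to -0.064) without WT mouse 5 or AKO mouse 3, triglyceride genes (-0.23 to -0.051) without WT mouse 4, WT mouse 5 or AKO mouse 3, lipolysis (-0.21 to -0.056) without WT mice 2 or 4 or AKO mice 3 or 9, and immediate-early genes (0.087 to 0.28) without WT mice 4 or 5 or AKO mice 3 or 9. Beyond the smaller number of mice, the cause was not tested. Medians moved by over 1.5 times, with the call kept, without WT mouse 2 (lipogenesis, -0.21), WT mouse 3 (adipocyte -0.42, triglyceride -0.23, lipolysis -0.21, macrophage 0.73), WT mouse 4 (lipid-associated 0.49, macrophage 0.28), AKO mouse 8 (adipocyte -0.30, triglyceride -0.18, immediate-early 0.28) and AKO mouse 11 (triglyceride -0.19, MHC class II 0.29). TPM keeps no depth, so what depth limits cannot be stated.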

Other observations

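The tests of this part were chosen after the values were seen. No summed immunoglobulin quantity passed a threshold of 0.05 between the groups. Summed kappa light chain genes held 474.0 ± 329.1 TPM in WT and 1338 ± 707.1 in AKO, lambda light chain genes 21.8 ± 11.4 and 124.1 ± 75.8, heavy chain variable genes 161.5 ± 121.6 and 480.5 ± 227.0, and Jchain, which joins IgA and IgM units and is made by antibody-secreting cells, 15.3 ± 11.9 and 43.4 ± 20.8. Exact permutation p-values were 0.0857, 0.0571, 0.0571 and 0.0857, each 0.107 after adjustment over 5 quantities. Ighm, the IgM heavy chain gene, was 756.6 ± 340.6 and 751.1 ± 109.1 TPM (exact permutation p = 0.886).

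Across the 8 mice the lipid-associated macrophage score was related to the mature adipocyte score, with r = -0.91 (exact permutation p = 0.000546, adjusted 0.00164 over 3 relations) and rho = -0.93 (p = 0.00223, adjusted 0.00670). Without the 2 mice farthest from the median, WT mouse 4 and AKO mouse 9, r was -0.86. Both groups hold only 4 mice, so no value within a group is given. The permutations took no account of genotype, although the group means of both scores differ. These were 7.72 in WT and 8.69 in AKO (macrophage) and 9.77 and 9.48 (adipocyte). TPM values share a fixed sum, which can tie abundant classes together, and how far it does so here was not tested. With the cell cycle score r was 0.78 (exact permutation p = 0.0168, adjusted 0.0253) and rho 0.76 (p = 0.0368, adjusted 0.0551), and r was 0.53 without the same 2 mice. With the endothelial score r was -0.62 (exact permutation p = 0.1003) and rho -0.67 (p = 0.0831), and r was -0.45 without those mice.

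Gstm6 lies in a cluster of mu class glutathione S-transferase genes on chromosome 3, with 29 tested genes between it and Slc16a1 in M21 order. Of its neighbours, Gstm1 had 1213 ± 180.7 TPM in WT and 900.8 ± 69.0 in AKO without overlap (log2 change -0.42, FDR = 0.831) and Gstm7 12.9 ± 7.80 and 6.64 ± 1.48 (FDR = 0.831), both short of the threshold. Gstm2 had 244.0 ± 43.7 and 213.6 ± 26.1, Gstm4 32.4 ± 6.79 and 27.5 ± 2.71, Gstm3 9.18 ± 6.51 and 10.51 ± 4.52, and Gstm5 48.2 ± 5.08 and 51.6 ± 24.8.

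Row 3 of Fabp4 may be a transcript made from the AP2-Cre transgene, whose promoter comes from that gene. The highest WT value, 0.340 TPM, is 6.53% of the lowest AKO value, 5.21 TPM, which the hypothesis allows. The test does not decide, because this row was picked from 33323 for separating the groups, and the sequence behind the row was not analysed here. GENCODE M21 lists 2 transcripts for Fabp4 against 3 rows here, so at least 1 row has no counterpart there, and which one is not known.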
